A study of Homo sapiens with 6 samples.

How the data were processed

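RNA from 6 cultures was measured on Illumina bead arrays, 1 vehicle and 1 PF-2341066 culture (0.8 µM, 24 h) of each of the lines BCBL1, BCP1 and BC1. Per the labels' protocols, total RNA was extracted with TRIzol, and cRNA was made with a TotalPrep kit and labelled with Cy3. The values used are the authors' deposited processed table, which holds linear probe intensity. The normalization method is not given in the sources used here. From the values, no log was taken and no background was subtracted, which makes folds smaller than the true ones, most of all for dim probes. The quantiles from 5 to 90% of both arrays of a line differed by at most 0.00294 on the log2 scale, against up to 0.0656 between any 2 of the 6 arrays, so that each line's pair looks normalized on its own. Scale and direction are not in doubt, since each column is a single-colour intensity.

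A second deposited table of non-normalized signal intensity and detection p-values has column names that match no sample label, and its 12 columns (6 of signal, 6 of detection p-values) were not used here. The planned background correction and detection filter were therefore replaced by the planned fallback: values were taken as normalized, log2 was applied, and a probe was kept when its mean log2 value lay above the median of all probe means (60.9 on the linear scale). The requirement of detection on both arrays for genes named per line could not be applied either.

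The table holds 47323 probes with 34 empty cells, and 47315 probes had a value on every array. A table of platform annotation gave 1 gene symbol to 30113 probes, several to 8 and none to 17202. By Entrez number, 30074 of the probes with 1 symbol matched the RefSeq gene table, and 0 symbols were changed. The filter kept 23657 probes, 16932 with 1 symbol, for 12552 genes. Where a gene had more than 1 kept probe (3405 genes), the brightest represented it. Among the 50 named genes with several kept probes, 7 had probes of opposite sign: CD68, DCN, GCLM, H2BC5, MCL1, OAS1 and TMPO.

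Inhibitor was compared with vehicle in limma 3.58.1 (R 4.3.3) with the line as a block, because the study's design sets each culture against its own vehicle. The moderated test was two-sided, with 2 residual and 8.63 prior degrees of freedom and a prior SD of 0.148 log2. Adjusted p-values are Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The pairing comes from the shared line: the deviations of both arrays of a line from their group means correlated at 0.772 in BCBL1, 0.824 in BCP1 and 0.907 in BC1. With 1 culture per line and arm, p-values measure only the spread between these cultures. Errors in the text are the SD over the line differences.

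Before the data were examined, 31 gene lists were fixed, and the 30 with 5 or more measured genes were tested with camera (preset correlation 0.01, Benjamini-Hochberg over 30 lists). Genes named in the text were chosen by a rule fixed at the same time. It takes MET and HGF; the 10 higher and 10 lower genes with the largest smallest-of-3-lines change among those past the threshold and moving the same way in all lines; up to 4 members of each list with the largest mean change; and the 3 highest and 3 lowest genes of each line. Other genes are named only where the text says so or in small counts. A further 8 lists, 1 of them in 2 forms, were chosen after the table of genes had been seen and were tested together as 9 list tests.

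The alternatives were quantile normalization over all arrays, normexp with an offset of 50 followed by quantile normalization, median scaling, no filter, the mean of a gene's probes, no block, limma-trend with robust moderation, array weights, each line left out, an estimated camera correlation, fry, a 1.5-fold threshold and only genes with a mean above the median gene. The stricter detection filter was not run. Chosen after seeing the data were a stricter filter that kept probes above the 75th percentile of probe means, normexp with an offset of 16, BCBL1 and BCP1 averaged as 1 line, and the fit without non-coding RNA genes.

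The fit was tested on simulated data for the main comparison over 12552 genes with 200 changed genes plus 1 shifted list. It recovered 96% of the genes changed by a log2 of 1 and 21% of those changed by 0.5, with 0 in the wrong direction. Of its calls on genes, 4.03% were of unchanged genes. The noise followed the fit's own variance model and was independent between arrays. That share therefore does not measure the error rate in the real data. Camera called the shifted list and 0 of 29 unshifted lists at the preset correlation, and did not call the shifted list with an estimated correlation. The simulated noise was independent between genes, while the estimated correlation in the real data reached 0.830 (G2/M and mitosis genes). The simulation therefore cannot show how often camera calls unchanged lists whose genes are correlated. Figures were drawn with matplotlib 3.10.9. No genome build is given in the sources used here, so no coordinates are printed.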

Results

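Gene expression was measured in 3 human primary effusion lymphoma lines, BCBL1, BCP1 and BC1, after exposure to the c-MET inhibitor PF-2341066 (crizotinib) or to vehicle. Primary effusion lymphoma is a B-lineage lymphoma of body cavities whose cells carry Kaposi's sarcoma-associated herpesvirus, and c-MET, the product of MET, is the receptor tyrosine kinase for hepatocyte growth factor, the product of HGF. Each line gave 1 vehicle array and 1 array of cells kept for 24 h with 0.8 µM inhibitor, so that 6 single-colour Illumina bead arrays formed 3 pairs. Probe intensity had a median between 60.6 and 61.6 on the 6 arrays, and its 75th percentile lay between 124.7 and 127.5. After the filter on dim probes, 12552 genes were tested. Nothing in the labels describes repeat cultures of a line, so errors are given over the 3 lines (SD, n = 3) and the number of arrays limits the precision.

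The vehicle arrays of BCBL1 and BCP1 lay close together. Their log2 intensities had a Pearson r of 0.990 across genes, above the r of 0.977 between the vehicle and inhibitor arrays of BCBL1 itself, while BC1 vehicle had an r of 0.924 with BCBL1 and 0.923 with BCP1. Between the vehicle arrays, 58 genes were 2-fold or more apart for BCBL1 and BCP1, against 1208 for BCBL1 and BC1 and 1214 for BCP1 and BC1. At 4-fold or more in both arms, the BCBL1 and BCP1 difference comprised 5 genes, CCN4, CD44, CYP26A1, ODAD3 and PFKFB4, named here after their values were seen, against 244 and 247 for the pairs with BC1. The pairs are counted as 3 lines, as labelled, and counts with BCBL1 and BCP1 averaged into 1 line are given beside the main ones.

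The first comparison asked which genes differed between inhibitor and vehicle across the 3 lines. Of 45 measured G1/S and DNA replication genes, 40 fell, and of 22 cholesterol synthesis and uptake genes, 15 rose, although as lists neither passed with an estimated correlation (adjusted p = 0.548 for each). Some abundant non-coding RNAs rose as well. HMGCS1, which makes the precursor of mevalonate, rose 5.09-fold (log2 change 2.35 ± 0.58, SD, n = 3), and RRM2, the regulatory subunit of ribonucleotide reductase, fell by 1.65 on the log2 scale (SD 0.55, n = 3). In limma with the line as a block, 760 genes were higher and 855 lower at a Benjamini-Hochberg adjusted p under 0.05, of which 759 and 852 moved the same way in all 3 lines. That agreement largely follows from the selection, since the test used the same 3 line differences. A mean change of 2-fold or more was reached by 45 of the higher and 69 of the lower genes. The counts depended on the lines: without BCP1 they were 178 higher and 197 lower, without BCBL1 454 and 569, and with BCBL1 and BCP1 averaged 519 and 625. With no block for the line, 1 gene was higher and 0 were lower, with 1113 genes at an unadjusted p under 0.05.

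Of the 10 genes with the largest increase shared by all lines, 7 were non-coding RNAs that lack a poly(A) tail. RN7SK, the scaffold of the complex that holds back the elongation factor P-TEFb, rose 7.22-fold (log2 2.85, with 4.01 in BCBL1 and 2.26 in BC1, limma adjusted p = 0.000769). The 18S ribosomal RNA probe RNA18SN5 (2.75 ± 1.10), the 5S ribosomal RNA probe RNA5S9 (2.74 ± 1.18), the U3 small nucleolar RNAs SNORD3D (2.36 ± 0.33), SNORD3A (1.99 ± 0.40) and SNORD3C (1.93 ± 0.28), and the U1 small nuclear RNA RNVU1-7 (2.15 ± 0.83) rose with it. The other 3 were HMGCS1, RGS1, a regulator of G protein signalling in lymphocytes (2.34 ± 0.43), and PIK3IP1, an inhibitor of PI3 kinase (1.65 ± 0.07). Labelling of cRNA from total RNA with this kit normally starts from poly(A) tails, so signals of RNAs without them also depend on RNA integrity and priming.

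The 10 genes with the largest shared decrease included replication and cell cycle genes. Besides RRM2, these were FBXO5, an inhibitor of the anaphase-promoting complex (−1.32 ± 0.28), POLE2, a subunit of DNA polymerase epsilon (−1.45 ± 0.43), the exonuclease gene EXO1 (−1.42 ± 0.32), the phosphatase gene CDC25A (−1.23 ± 0.26) and the kinase gene CDC7 (−1.07 ± 0.11). MUC1, a membrane mucin (−1.54 ± 0.40), FABP5, a fatty acid binding protein (−1.50 ± 0.43), FAM81A (−1.30 ± 0.40) and TMPO, a protein of the inner nuclear membrane (−1.30 ± 0.29), completed the set. The limma adjusted p of these 10 genes lay between 0.000769 for EXO1 and MUC1 and 0.000905 for FAM81A. Of the 3 TMPO probes above the filter, the 2 brighter were lower in all lines and the dimmest, near background, was not.

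**Figure D1:**
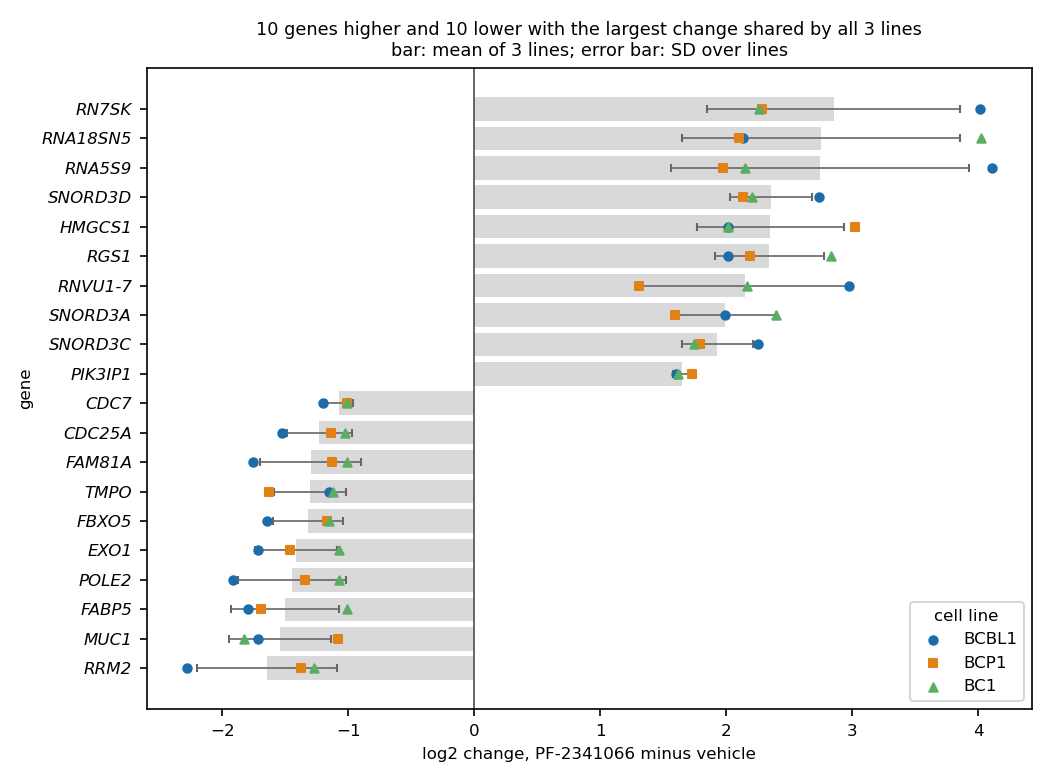
Horizontal bars give the mean log2 change (PF-2341066 minus vehicle, x axis) of the 10 genes higher and the 10 genes lower with the largest change shared by all 3 lines, with the SD over lines as error bars and a point for each line. RN7SK and RNA5S9 stood highest in BCBL1, at 4.01 and 4.11, and RNA18SN5 stood highest in BC1, at 4.02.

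MET itself was not distinguishable between the arms (−0.13 ± 0.17, limma adjusted p = 0.524). Its probe read 432.3 in BCBL1, 408.3 in BCP1 and 201.5 in BC1 under vehicle. HGF was not distinguishable either (−0.16 ± 0.15, adjusted p = 0.417), and its vehicle intensity of 54.5 in BCBL1 and 56.8 in BCP1 lay under the filter value of 60.9, against 214.7 in BC1. Among 18 measured genes of the MET receptor and its proximal partners, 1 rose and 2 fell (1 and 2 adjusted over the list alone). MST1, which encodes a ligand of the related receptor RON, rose (1.35 ± 0.30), CD44 (−0.78 ± 0.36) and the phosphatase gene PTPN11 (−0.39 ± 0.13, adjusted p = 0.0494) fell, and SEMA4D stood at −0.42 ± 0.46 without passing. Both CD44 values of BCP1 (52.2 and 40.3) lay under the filter value of 60.9, so only BCBL1 (−0.95) and BC1 (−1.03) inform on CD44, and PTPN11 passed in 8 of 15 other settings. The list median was −0.08 (camera adjusted p = 0.222). Of 9 measured genes of other kinases bound by the inhibitor, AURKA fell (−0.77 ± 0.48), as 1 lower call both over all genes and adjusted over the list alone, but did not pass without BCP1 (−0.51, adjusted p = 0.123). MERTK (0.41 ± 0.42), TYRO3 (−0.29 ± 0.16) and JAK2 (−0.09 ± 0.18) did not pass, although MERTK did without BC1 (0.63, adjusted p = 0.000746), and the list median was −0.04 (camera adjusted p = 0.550). Both MERTK values of BC1 (55.6 and 54.9) lay under the filter value, so BC1 does not inform on this probe. The other kept MERTK probe, which is dimmer, had a mean change of 0.35. ERK output genes had a median of 0.01 over 20 genes (camera adjusted p = 0.596), with JUNB lower (−0.46 ± 0.15) as the 1 call, over all genes and adjusted over the list alone. FOSB (1.01 ± 1.17), FOS (0.79 ± 0.97) and EGR1 (0.62 ± 0.65) did not pass, since their values of 2.35, 1.90 and 1.37 in BCBL1 were not matched in the other lines. In BC1 the vehicle value of FOS (56.7) lay under the filter value and that of FOSB (62.4) just above it, so their changes in BC1 are not exact.

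Of the 30 gene lists tested with limma's camera at its preset correlation of 0.01, 4 were lower and 4 higher at an adjusted p under 0.05. With a correlation estimated for each list, 0 lists passed, and the adjusted p of these 8 lay between 0.548 and 0.564. This form of camera takes its degrees of freedom from the fit, here 2, while the preset form takes them from the number of genes. In the simulated data, with independent noise, the estimated form also missed the shifted list. A miss therefore does not show that a list is unchanged. For MYC and ribosome biogenesis genes the estimated correlation (−0.00414) lay under the preset one. Their unadjusted camera p still rose from 3.07e-08 to 0.0233. For that list the loss was thus not due to correlation between genes but came with the fewer degrees of freedom. The lists were fixed before the data were examined.

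G1/S and DNA replication genes had a median log2 change of −0.73 (line medians −0.94, −0.79 and −0.57 in BCBL1, BCP1 and BC1). Of 45 measured genes, 40 fell and 0 rose, and 42 fell adjusted over the list alone (camera adjusted p = 1.96e-30; adjusted p = 0.548 with an estimated correlation). TYMS, the thymidylate synthase gene, fell by 1.19 (SD 0.22, n = 3) and UHRF1, which recruits maintenance DNA methylation, by 1.17 (SD 0.38). G2/M and mitosis genes had a median of −0.71, with line medians of −0.68, −1.16 and −0.33, and 34 of 46 fell, or 41 adjusted over the list alone (camera adjusted p = 7.15e-25; adjusted p = 0.564 with an estimated correlation). SPC25 (−1.20 ± 0.36), a kinetochore gene, ASPM (−1.17 ± 0.50), KIF11 (−1.16 ± 0.34) and TPX2 (−1.11 ± 0.46), genes of the mitotic spindle, had the largest mean decreases. DNA damage response and repair genes had a median of −0.29 (−0.44 with a stricter filter on dim probes), and 19 of 41 fell, also 19 adjusted over the list alone (camera adjusted p = 7.80e-11; adjusted p = 0.548 with an estimated correlation). EXO1, H2AX (−1.15 ± 0.40), RAD51AP1 (−0.94 ± 0.18) and FANCI (−0.92 ± 0.37) changed most. MYC and ribosome biogenesis genes had a median of −0.21, and 12 of 36 fell, or 13 adjusted over the list alone (camera adjusted p = 1.84e-07; adjusted p = 0.548 with an estimated correlation). Their lowest members were ODC1, the rate-limiting enzyme of polyamine synthesis (−1.06, −1.04 and −0.90 in BCBL1, BCP1 and BC1), CAD, an enzyme of pyrimidine synthesis (−0.68 ± 0.37), and the nucleolar protein genes NOLC1 (−0.64 ± 0.09) and NOP56 (−0.55 ± 0.04).

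Cholesterol synthesis and uptake genes had the highest list median, 0.88, with line medians of 0.56 in BCBL1 and 0.75 in BC1 and the highest in BCP1 (SD 0.22 over lines). Of 22 measured genes, 15 rose and 0 fell, also 15 and 0 adjusted over the list alone (camera adjusted p = 4.80e-13; adjusted p = 0.548 with an estimated correlation). After HMGCS1 came MSMO1 (1.68 ± 0.78) and LSS (1.59 ± 0.53), which act late in sterol synthesis, and INSIG1, which retains the SREBP machinery in the endoplasmic reticulum (1.53 ± 0.50). NF-kappaB target genes had a median of 0.41, with line medians of 0.27, 0.62 and 0.10, and ran from 0.16 with no filter on dim probes to 0.64 with a stricter one. Of 24 genes, 11 rose and 1 fell, or 12 and 2 adjusted over the list alone (camera adjusted p = 7.79e-05; adjusted p = 0.548 with an estimated correlation), and the call was lost with no block for the line (adjusted p = 0.0834). The cytokine gene LTB (1.49 ± 0.87), the inhibitor gene NFKBIA (0.95 ± 0.90), RELB (0.87 ± 0.54) and TNFAIP3 (0.84 ± 0.15) rose, although NFKBIA stood at −0.03 in BC1 and did not pass without BCBL1 (0.55, adjusted p = 0.0643). The vehicle values of LTB in BCBL1 (48.4) and BCP1 (54.4) lay under the filter value of 60.9, so its mean change is not exact. Lysosome and autophagy genes had a median of 0.28. Of 39 genes, 13 rose and 1 fell, also 13 and 1 adjusted over the list alone (camera adjusted p = 4.69e-06; adjusted p = 0.564 with an estimated correlation). SQSTM1, an autophagy receptor (1.44, 0.74 and 0.81 in BCBL1, BCP1 and BC1), NPC2 (0.97 ± 0.44) and NPC1 (0.88 ± 0.20), which export cholesterol from lysosomes, rose. The sialidase gene NEU1 (0.73 ± 0.73, adjusted p = 0.0459) passed as well, but its change came mostly from BC1 (1.58, against 0.35 in BCBL1 and 0.28 in BCP1), was 0.31 without BC1, and passed in only 5 of 15 other settings. CDK inhibitors and arrest genes had a median of 0.23, between 0.11 without BC1 and 0.30 over the other settings. Of 17 genes, 7 rose and 2 fell, also 7 and 2 adjusted over the list alone (camera adjusted p = 0.00879; adjusted p = 0.548 with an estimated correlation). TXNIP (1.11 ± 0.50), KLF6 (1.02 ± 0.48), FOXO3 (0.63 ± 0.43) and CDKN1A, which encodes p21 (0.68 ± 0.62), rose, with CDKN1A at 0.02 in BCBL1 and 1.24 in BC1. CDKN1A did not pass without BC1 (0.39, adjusted p = 0.0590), nor FOXO3 without BCBL1 (0.39, adjusted p = 0.126).

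**Figure D2:**
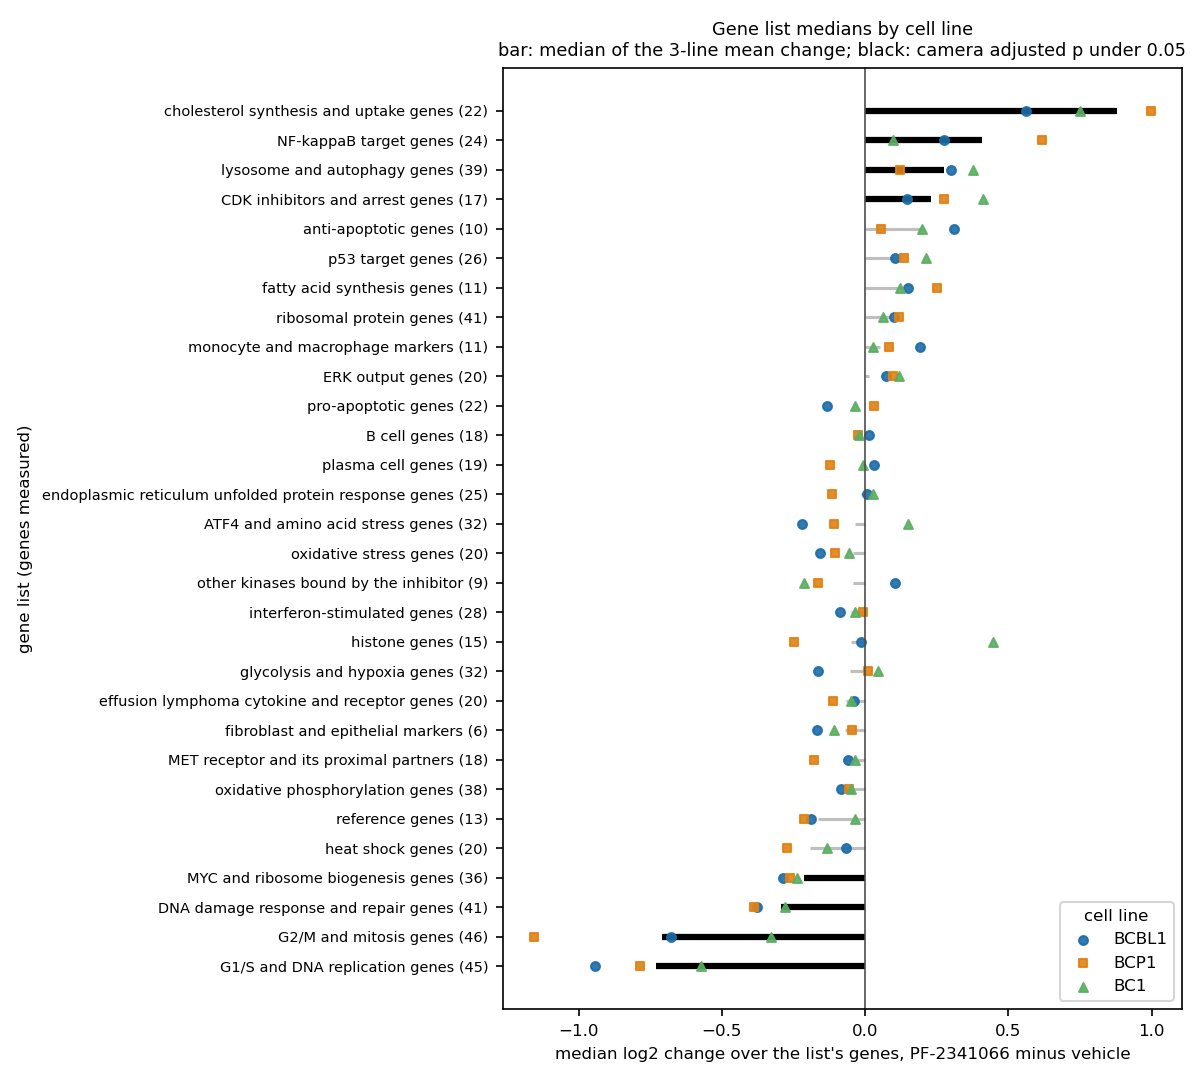
Each row is a gene list with the number of genes measured, the x axis is the median log2 change over its genes (PF-2341066 minus vehicle), bars give the median of the 3-line mean changes and points the median in each line. Black bars mark the 8 lists with a camera adjusted p under 0.05, from cholesterol synthesis at 0.88 to G1/S and DNA replication at −0.73, and 0 of the 8 pass with an estimated correlation (adjusted p from 0.548 to 0.564).

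The other 22 lists did not pass. The series title names apoptosis. Pro-apoptotic genes had a median of 0.00 over 22 genes (camera adjusted p = 0.992), with TNFRSF10B, a death receptor gene, higher (0.59 ± 0.08) and its ligand gene TNFSF10 lower (−0.44 ± 0.19), 1 call each way over all genes and adjusted over the list alone. BAK1 (−0.40 ± 0.26) and HTRA2 (−0.32 ± 0.13) did not pass. Anti-apoptotic genes had a median of 0.20 over 10 genes (camera adjusted p = 0.185). TNFAIP3 and CFLAR (0.67 ± 0.19) rose, while BIRC5 (−0.65 ± 0.73) and MCL1 (0.32 ± 0.17) did not pass; adjusted over the list alone, 2 rose and 1 fell. Kept probes of MCL1 differed in sign. BIRC5 stood at −0.87, −1.24 and 0.17 in BCBL1, BCP1 and BC1 and passed without BC1 (−1.06, adjusted p = 6.80e-10). p53 target genes had a median of 0.13 (camera adjusted p = 0.0778), passed in 5 of 15 other settings (lowest adjusted p = 0.00818, without BCBL1) and reached a median of 0.26 with a stricter filter. The main setting gave adjusted p = 0.564 with an estimated correlation. Among them, 4 of 26 rose and 1 fell, or 5 and 1 adjusted over the list alone. TP53INP1 (1.02 ± 0.40) rose and DDB2 (−0.71 ± 0.42) fell. Fatty acid synthesis genes had a median of 0.13 (camera adjusted p = 0.0876), and 5 of 11 rose and 1 fell, or 5 and 2 adjusted over the list alone. ACSS2 (1.15 ± 0.25), ELOVL6 (0.92 ± 0.32), FASN (0.81 ± 0.17) and SCD (0.80 ± 0.54) were its highest members, and SCD did not pass without BCP1 (0.49, adjusted p = 0.117).

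Among stress lists, ATF4 and amino acid stress genes had a median of −0.03 over 32 genes (camera adjusted p = 0.620), with 2 higher and 4 lower, or 2 and 6 adjusted over the list alone. PPP1R15A (1.58 ± 0.61) and DDIT3 (1.14 ± 0.28), which respond to translational stress, rose, and the amino acid transporter genes SLC7A5 (−0.72 ± 0.58) and SLC1A5 (−0.68 ± 0.07) fell. Endoplasmic reticulum unfolded protein response genes had a median of −0.01 and a mean of 0.02 over 25 genes (camera adjusted p = 0.992), with 3 higher and 2 lower, or 4 and 3 adjusted over the list alone. The chaperone gene DNAJB9 (0.88 ± 0.22), SELENOS (0.68 ± 0.04) and CRELD1 (0.59 ± 0.20) rose and CALR (−0.60 ± 0.15) fell. Heat shock genes had a median of −0.19 over 20 genes (camera adjusted p = 0.178), with 1 higher and 2 lower, the same counts adjusted over the list alone. DNAJB6 (0.93 ± 0.11) rose by its brightest probe, but its other kept probe (mean intensity 1121) stood at 0.09. HSPD1 (−0.43 ± 0.18) and HSP90AA1 (−0.39 ± 0.15) fell, and HSPH1 stood at −0.34 ± 0.32. Oxidative stress genes had a median of −0.04 over 20 genes (camera adjusted p = 0.266), with 3 lower, also 3 adjusted over the list alone. PRDX1 (−0.60 ± 0.34), GCLM (−0.45 ± 0.29) and TALDO1 (−0.42 ± 0.01) fell, and MT1F stood at 0.41 ± 0.65. The call of GCLM held in only 6 of 15 other settings, and those of SLC7A5 and HSP90AA1 in 9 each. Glycolysis and hypoxia genes had a median of −0.05 and a mean of 0.04 over 32 genes (camera adjusted p = 0.887), with 6 higher and 2 lower, or 7 and 3 adjusted over the list alone. PFKFB4 (0.95 ± 0.39), ALDOC (0.73 ± 0.64) and KDM3A (0.62 ± 0.23) rose and PGAM1 (−0.58 ± 0.46) fell. ALDOC did not pass without BC1 (0.40, adjusted p = 0.0543), nor PGAM1 without BCBL1 (−0.31, adjusted p = 0.232).

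Ribosomal protein genes had a median of 0.09 over 41 genes (camera adjusted p = 0.0778), with 4 higher and 1 lower, or 3 and 1 adjusted over the list alone. RPL37 (0.87 ± 0.55), RPL28 (0.62 ± 0.53) and RPS9 (0.45 ± 0.13) rose and RPL29 (−0.64 ± 0.29) fell, while RPL28 did not pass without BCBL1 (0.36, adjusted p = 0.184). Oxidative phosphorylation genes had a median of −0.08 over 38 genes (camera adjusted p = 0.296). ATP5MC1 (−0.48 ± 0.22) was the 1 gene that fell, with its call kept in 9 of 15 other settings, and 0 passed adjusted over the list alone. NDUFS7 (0.35 ± 0.21), ATP5MC3 (−0.35 ± 0.09) and NDUFA9 (−0.30 ± 0.12) did not pass. Interferon-stimulated genes had a median of −0.05 over 28 genes (camera adjusted p = 0.828), with 2 higher and 2 lower, or 3 and 2 adjusted over the list alone. ISG20 (0.85 ± 0.10) and OAS1 (0.44 ± 0.10) rose, and IFI35 (−0.58 ± 0.29) and PARP9 (−0.50 ± 0.18) fell. Histone genes had a median of −0.05 and a mean of 0.13 over 15 genes, with camera's direction upward (adjusted p = 0.365). With a stricter filter on dim probes, chosen after the data were seen, the median turned to 0.76 and the list passed at the preset correlation (adjusted p = 0.0385), while the main setting gave adjusted p = 0.846 with an estimated correlation. Of these genes, 5 rose and 2 fell, or 6 and 3 adjusted over the list alone. H2BC21 (1.22 ± 0.35), H2BC5 (1.02 ± 0.10) and H2AC6 (0.87 ± 0.21) rose and H2BC9 (−1.12 ± 0.55) fell. Kept probes of H2BC5, OAS1 and GCLM differed in sign, and the values given are those of the brightest probe.

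Plasma cell genes had a median of −0.01 over 19 genes (camera adjusted p = 0.386), with 2 higher and 5 lower, the same counts adjusted over the list alone. MUC1, FKBP11 (−0.97 ± 0.12) and SDC1, which encodes the plasma cell antigen CD138 (−0.70 ± 0.40), fell, and SLAMF7 (0.57 ± 0.30) rose. B cell genes had a median of 0.00 over 18 genes (camera adjusted p = 0.887). SYK (−0.75 ± 0.28) was the 1 call, over all genes and adjusted over the list alone, and CD37 (−0.42 ± 0.41), CD79B (0.35 ± 0.26) and BLNK (0.33 ± 0.19) did not pass, although CD37 did without BC1 (−0.65, adjusted p = 0.000480). Effusion lymphoma cytokine and receptor genes had a median of −0.07 over 20 genes (camera adjusted p = 0.845), with 4 higher and 3 lower, or 6 and 4 adjusted over the list alone. Over the other settings this median ran from −0.11 to 0.38, and the list passed in 0 of 15. IL6 (0.58 ± 0.31) and its signalling receptor gene IL6ST (0.64 ± 0.10) rose, and AQP3 (−1.10 ± 0.79) and CD44 fell. Of the markers of other cell types, 0 of 11 monocyte and macrophage markers passed, over all genes or adjusted over the list alone (median 0.05, camera adjusted p = 0.395). CST3 (0.29 ± 0.14), CD68 (0.23 ± 0.11), FCN1 (0.20 ± 0.20) and LYZ (0.19 ± 0.23) stood highest. Of 6 fibroblast and epithelial markers, VIM, which lymphoid cells also express, fell (−0.65 ± 0.21) as the 1 call on either adjustment (median −0.07, camera adjusted p = 0.296), and KRT18 (−0.15 ± 0.12), KRT8 (−0.08 ± 0.16) and DCN (−0.06 ± 0.04) did not pass. T and NK cell markers had 4 measured genes, too few for the set test, and 0 passed, adjusted over all genes or adjusted over the list alone. These were ZAP70 (−0.12 ± 0.23), LCK (−0.04 ± 0.30), IL7R (−0.03 ± 0.24) and CD2 (0.02 ± 0.11). Of 13 reference genes, TUBB fell (−0.95 ± 0.20) as the 1 call on either adjustment, and HPRT1 (−0.38 ± 0.32), POLR2A (−0.38 ± 0.33) and ACTB (−0.31 ± 0.39) did not pass (median −0.17, camera adjusted p = 0.0876), although ACTB did without BC1 (−0.53, adjusted p = 0.00602).

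The second comparison set each inhibitor culture beside the vehicle culture of its own line. With 1 array per arm there is no test within a line. In BCBL1, 118 genes were higher and 180 lower by 2-fold or more. In BCP1 the counts were 73 and 155, and in BC1 they were 72 and 31. With normexp at offset 16, chosen after the data were seen, 188, 120 and 109 genes were higher in BCBL1, BCP1 and BC1, and 60 lower in BC1. The genes highest in BCBL1 were RNA5S9 (4.11), RN7SK (4.01) and the U1 RNA gene RNU1-3 (3.02). ZCCHC12 (−2.75), H3C12 (−2.44) and PTP4A3 (−2.35) were lowest in BCBL1 and also in BCP1, at −2.22, −2.19 and −2.05, with −0.08, −0.40 and −0.41 in BC1. Their vehicle intensity in BC1 was only 49.6 (under the filter value of 60.9), 86.6 and 94.9, which left little or no room to fall. In BCP1 the highest genes were HMGCS1 (3.02), MSMO1 (2.57) and LTB (2.38), the last from a vehicle value under the filter value, so that its fold and rank are not exact. In BC1 they were RNA18SN5 (4.02), RGS1 (2.83) and the U4 RNA gene RNU4-1 (2.73), and the lowest were MUC1 (−1.83), SAA2 (−1.51) and DHRS2 (−1.50). Differences between lines were not tested. In all 3 lines together, 20 genes were higher and 11 lower by 2-fold or more (6 lower with the mean of a gene's probes). Independent lines would give 0.00394 and 0.00549, and the genes shared by BCBL1 and BCP1, with BC1 alone independent, 0.195 and 0.185. HMGCS1, INSIG1, LSS, MSMO1, PIK3IP1 and RGS1 were among the 20, and RRM2, CDC25A, CDC7, EXO1, FBXO5 and POLE2 among the 11. The 20 also held RN7SK, RNA18SN5, RNA5S9, the U3 entries SNORD3A, SNORD3C and SNORD3D, and RNVU1-7, RNU1-3 and other U1 entries. Signals of these RNAs also depend on RNA integrity and priming, and U1 and U3 entered repeatedly, so the 20 are not as many separate responses.

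The third comparison asked how alike the lines responded. Across the 12552 genes, which are not independent replicates, the log2 changes of BCBL1 and BCP1 had a Pearson r of 0.665 and a Spearman rho of 0.560. For BCBL1 and BC1 these were 0.505 and 0.426, and for BCP1 and BC1 0.505 and 0.424. The lines share no control array. Of the sum of squares of the log2 values, the line took 79.6%, the treatment 14.4% and the remainder 6.01%, and without BC1 the shares were 36.0%, 53.1% and 10.9%.

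**Figure D3:**
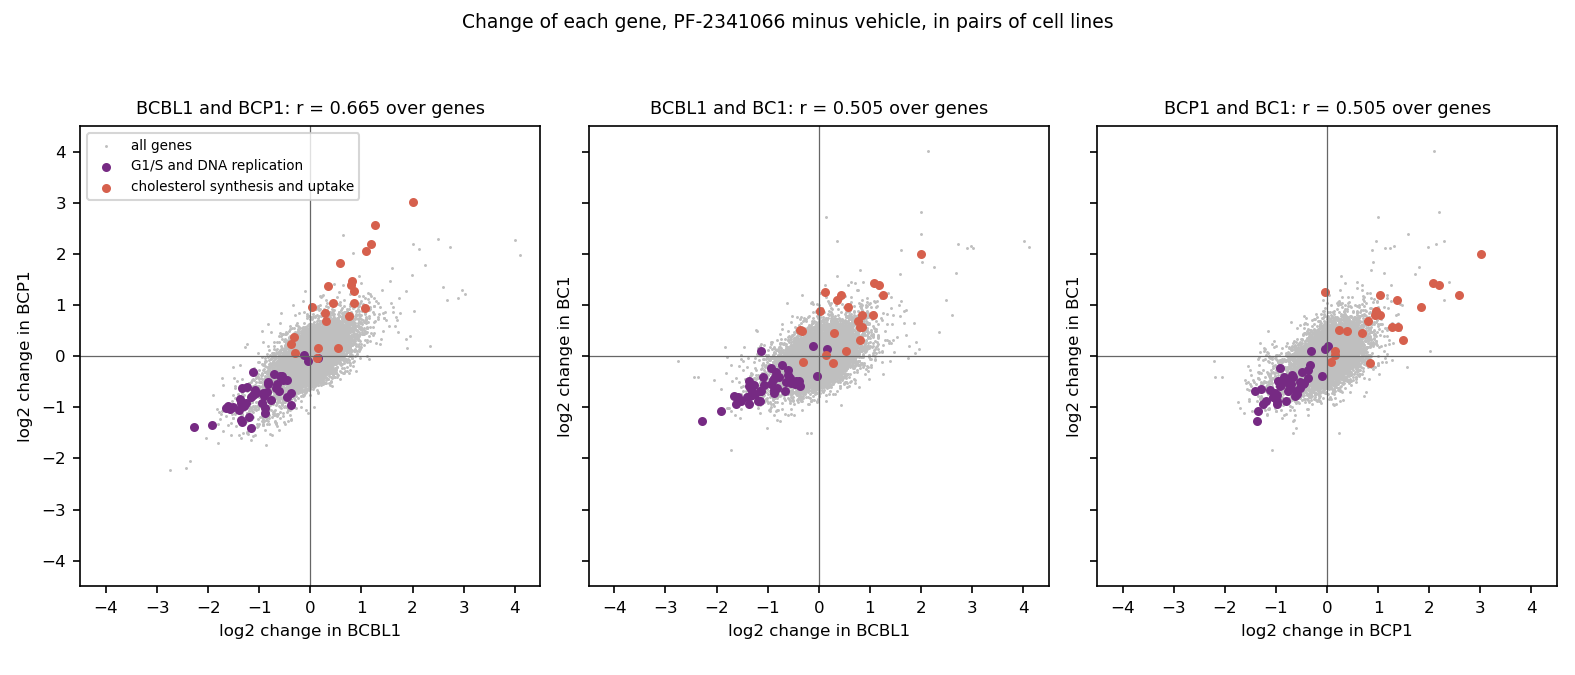
Each panel plots the log2 change (PF-2341066 minus vehicle) of every tested gene in a pair of lines, grey for all 12552 genes, purple for the 45 G1/S and DNA replication genes and red for the 22 cholesterol synthesis and uptake genes. Most purple points lie at lower left and most red points at upper right, with r of 0.665, 0.505 and 0.505 over genes.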

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

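In this part the size that counts as movement, 0.209 on the log2 scale (the prior SD times the square root of 2), and all tests but the counts of sample splits were chosen after the results were seen. With 3 samples per group no sample was tested for standing apart from its group.

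The median of histone genes was −0.25 in BCP1 and 0.45 in BC1, a gap of 0.69. As 7 of the 15 genes were higher and 3 lower in all 3 lines, the gap is in the median of a mixed list and does not show the group moving in opposite directions. The T cell kinase gene LCK stood at 0.26 in BCBL1 and −0.35 in BC1, a gap of 0.61, but at intensities near background, and its other kept probe ran the opposite way (−0.20 in BCBL1 and 0.10 in BC1), so no direction can be read for LCK. SAA2 stood at 0.23 in BCP1 and −1.51 in BC1, a gap of 1.74, but both SAA2 values of BCP1 (47.4 and 55.7) lay under the filter value of 60.9, so only the decrease in BC1 can be read. Each line has 1 array per arm, so these differences were not tested.

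In the 10 splits of the 6 arrays into 3 and 3, each fitted with the line as a block, the real split gave 1615 genes past the threshold and the highest of the others 0, with 1 split of 10 as large. For gene lists the real split gave 8 and the highest of the others 10, with 7 of the 10 splits as large. The design cannot give a share under 0.05 with 10 splits. Among the 4 splits that part all 3 pairs, the highest other gave 0 genes and 7 lists. The other 6 part 1 pair only, so that 1 line alone carries the contrast, which is its inhibitor difference apart from the sign. Camera with the preset correlation called 9 or 10 lists in each of those 6 splits, more than in the real one. The others among the 4 hold the inhibitor difference with 1 line reversed. Where the inhibitor has an effect, it thus enters every split, as contrast or as error that lowers the gene count. The splits therefore cannot show how many genes or lists would be called without an effect.

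Some structural non-coding RNAs, but not all classes of them, were higher under PF-2341066. Among those above the 75th percentile of probe means, 12 of 13 transcripts of RNA polymerases I and II rose. The median log2 change of the 13 was 1.93. This class includes RNA18SN5 and the U1 and U3 RNAs whose rise prompted the question, with repeat entries for U1 and U3. The cut used both arms, so a rise itself could lift dim members such as SNORD13 (mean vehicle intensity 97.8) over it. The class was thus no independent test of more transcription by RNA polymerase III alone. In this class outside U1, U3 and RNA18SN5, RNA28SN5 (1.52), RNU4-1 (1.29), RNU4-2 (1.19) and SNORD13 (0.92) rose, and RNU11 (0.34) did not pass. The 29 intron-encoded small nucleolar and Cajal body RNAs, which also lack poly(A) tails, had a median of 0.15 (quartiles −0.09 and 0.35), which argues against a difference in priming or recovery that acts alike on all such RNA. Of 6 polymerase III transcripts (median 0.45), RN7SK, RNA5S9 and RNU6-1 (0.61, limma adjusted p = 0.00760) rose, and RNY3 (0.29), RN7SL1 (0.11) and RNY1 (−0.43) did not pass. A difference in RNA integrity that acts on some of these RNAs, and an effect of the inhibitor, stay open as untested.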

How the results depend on the processing

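Tests with the stricter filter on probes (above the 75th percentile), normexp at offset 16, BCBL1 and BCP1 as 1 line and no non-coding RNA genes were chosen after seeing the data. Of the 8 called lists, 7 stayed past the threshold in all 15 settings that kept the preset correlation, and NF-kappaB targets in 14. Median scaling shifts both arrays of a line alike and so moved no treatment value. The authors' value table served as the main values, and detection p under 0.01 was not run. Without the replicate block, 1 gene was higher and 0 lower. Leaving out each line in turn gave 178 to 1062 higher and 197 to 1124 lower genes, and shares of variation of 36.0 to 82.5% for line, 13.1 to 53.1% for treatment and 4.35 to 10.9% for the rest; fewer lines leave fewer residual degrees of freedom, yet the counts without BC1 were the highest, and the cause was not tested. An estimated correlation left 0 higher and 0 lower lists, and fry, which does not compare a list with other genes, 0 and 2 (oxidative stress and MYC lists). At 1.5-fold, BCBL1 had 679 higher and 780 lower genes, BCP1 458 and 589, BC1 419 and 384, and all lines together 108 and 134. In genes with a mean above the median gene, rho for BCBL1 and BCP1 was 0.677, r and rho for BCBL1 and BC1 0.612 and 0.556, and for BCP1 and BC1 0.612 and 0.560. With no filter the rho values were 0.426, 0.314 and 0.317, and with the stricter filter 0.665, 0.533 and 0.538 in that order of pairs. With the mean of a gene's probes, 6 genes were lower by 2-fold or more in all lines, against 11. Normexp at offset 16 gave 473 higher genes, and 188 (BCBL1), 120 (BCP1) and 109 (BC1) higher and 60 (BC1) lower by 2-fold. The histone median turned from −0.05 to 0.76 with the stricter filter, where the list passed at the preset correlation (adjusted p = 0.0385; main setting, adjusted p = 0.846 with an estimated correlation). Of lists not called, p53 targets passed in 5 of the 15 settings, reference genes in 3, and ribosomal protein and fatty acid synthesis genes in 2 each, all at the preset correlation (p53 targets, main setting: adjusted p = 0.564 with an estimated correlation). The cause of these shifts was not tested. Of the 108 named genes past the threshold, 107 lost it with no block and 43 without BCP1. Of all 144 named genes, 0 changed sign while called, and 25 values without a call on either side changed sign. The block changed no other list call except for ribosomal proteins (adjusted p = 0.0241 without it). Signal near background limits dim genes.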

Other observations

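The tests of explanations in this part were chosen after the data had been seen, except the comparison of genes that vary between people, whose list and rule were written before its values were looked at. The settings reused for cholesterol genes were planned, apart from the stricter filter and normexp at offset 16. The further gene lists were also picked after the table of genes had been seen, so their p-values are descriptive, and genes named with them were chosen after their values were seen. In 9 list tests with limma's camera, nuclear pore genes had a median log2 change of −0.26 and 10 of 26 fell (adjusted p = 3.74e-07; adjusted p = 0.304 with an estimated correlation). NUP85 stood at −0.80 and NUP205 at −0.78. Tubulin genes had a median of −0.54, with 6 of 12 lower and 1 higher (adjusted p = 2.54e-05; adjusted p = 0.304 with an estimated correlation), among them TUBA1C (−1.08) and TUBB4B (−0.93). Proteasome genes had a median of −0.18 with 6 of 27 lower (adjusted p = 1.87e-04; adjusted p = 0.399 with an estimated correlation). Mitochondrial ribosomal protein genes had a median of −0.14 with 6 of 52 lower (adjusted p = 9.20e-04; adjusted p = 0.399 with an estimated correlation). Genes of hnRNP and SR splicing factors had a median of −0.16 with 5 of 27 lower and 2 higher (adjusted p = 0.0152; adjusted p = 0.304 with an estimated correlation), and SRSF5 (0.76) and HNRNPDL (0.59) were the 2 that rose. Rab GTPase genes, a mixed list that included endosomal members, had a median of 0.19 with 7 of 24 higher and 1 lower. Their camera adjusted p was 0.00317, and 0.304 with an estimated correlation. RAB2B (0.76) and RAB5B (0.72) were among those that rose, and RAB27A fell (−0.67).

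A hypothesis was that cholesterol genes rose because less sterol reached the cytosol, which may follow from the known build-up of basic lipophilic drugs in lysosomes. Across 6 other settings (scaling, background correction, filter or the mean of a gene's probes) the list passed each time, with a lowest median of 0.76. In the main setting its camera adjusted p was 0.548 with an estimated correlation. The passes argue against those processing choices as the whole cause. Both arrays of a line already agreed in their quantiles from 5 to 90%, so new scaling could change little. The authors' own normalization was not varied. Less cytosolic sterol would lower LXR target genes. These had a median of −0.17 over 10 genes, with ABCA1 lower (−1.37) and NR1H3 higher (0.37), and missed the threshold (camera unadjusted p = 0.0702, adjusted p = 0.0790; adjusted p = 0.399 with an estimated correlation), so the test leaves the hypothesis open. The LXR medians were −0.32 in BCBL1, −0.24 in BCP1 and 0.04 in BC1, with ABCA1 at −0.47 in BC1, and no test was possible within a line. A difference in medium or density between the cultures of a line cannot be told apart from the drug, because there is 1 vehicle culture per line.

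The rise of PIK3IP1, TSC22D3 (1.96), TXNIP and KLHL24 (0.96) prompted the hypothesis that FOXO target genes rose as a group, and the result depends on how the list is drawn. As first written, with 26 measured genes that included KLHL24, HBP1 and CDKN1A, which were among the higher genes already seen, the list gave an unadjusted p of 0.0470 and an adjusted p of 0.0605 (median 0.13, 6 higher and 3 lower). After that result was known, those genes were removed, and the remaining 23 gave an unadjusted p of 0.334 and an adjusted p of 0.334 (median 0.07, 3 higher and 3 lower). Neither form passed after adjustment, and with an estimated correlation the adjusted p was 0.304 and 0.399. The hypothesis is not decided by these data.

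The likeness of BCBL1 and BCP1 bears on how independent the 3 pairs are. The authors' normalization is not enough to account for it, since BC1, from the same table, differed from BCP1 by 2-fold or more at 1214 genes, against 58. Of 20 measured genes whose level is known to differ between people, 0 were 2-fold or more apart between BCBL1 and BCP1 in both arms, against 6 between BCBL1 and BC1 and 6 between BCP1 and BC1, among them GSTT1 and HLA-DRB1. Of the 20, 9 were too dim in both BCBL1 and BCP1 (under 2 times the filter value, a limit chosen after their levels were seen) for such a gap to show, which leaves 0 of 11. HLA-DQB1 and MYOM2, counted among the gaps with BC1, were among those 9. HLA-DRB1, HLA-DRB4 and HLA-DRB5, all class II genes, made up much of the rest. GSTM1, GSTM2, ERAP2, CHURC1, PSPH and POMZP3 were bright enough but separated no pair of lines, so the contrast with BC1 is weaker than 0 against 6. In BC1, HLA-DRB1 (60 under vehicle, 63.6 under inhibitor) and HLA-DRB5 (57.4 and 59.2) lay near the filter value. Outside class II, only GSTT1 and HSD17B12 of the bright genes set BC1 apart from BCBL1 and BCP1. These are too few to tell cells of 1 donor from cells of different donors. That both labels hold cells of 1 line is thus neither shown nor excluded, and stays a hypothesis. Lines of similar state could look alike in the 20 genes, and class II genes such as HLA-DRB1 vary with cell state as well. On the other side, 37 genes were 2-fold or more apart between BCBL1 and BCP1 in both arms. Of these, CCN4, CD44, CYP26A1, ODAD3 and PFKFB4 were 4-fold or more apart, so genotypes would be needed to settle it.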
